A study of Homo sapiens with 18 samples.

How the data were processed

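RNA was measured in K562, KMS34 and HEK293 cells after 44 h with 12 µM of a scramble or an ncpCUL1-targeting antisense oligonucleotide, with 3 libraries in each of 6 groups. Per the labels, RNA was extracted with Trizol and the libraries were poly(A) selected and non-directional, so strand cannot separate overlapping genes. The submitters' processing notes name STAR alignment and the hg38 build without a version. They do not name the read counter or the annotation release. The labels give no sequence or position for either oligonucleotide.

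The deposited table is named as raw counts, but its values are RPKM, reads per kilobase of coding length, scaled by the counted reads of the library, which the authors computed before deposit. This was read from the values themselves. Dividing out 1 factor per library and a length per gene, whole for 99.9% of genes, turned each value into a whole number of reads, to within 0.01 read, for all 17822 genes with a value in at least 2 libraries. A further 393 genes had a value in 1 library and 1253 were at 0 in all 18, of 19468 listed. At least 99.995% of each library total was recovered. Of the recovered lengths 85.2% were divisible by 3, and that of GATA1 was 1242 nucleotides, so they were read as coding lengths without a check of every gene. Column sums differed between libraries, from 874637 to 967969. No scaling between libraries had been applied. Recovery was tested on simulated data, where reads came back for 2942 of 2943 genes. Gene identifiers were joined to RefSeq on GRCh38.p14, with 19421 matched.

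The library totals ran from 19682322 to 29386747 reads. At this depth RPKM near the filter rests on few reads, and the spread between replicates limits the larger values. Within groups, log2 values correlated at 0.988 to 0.997 across genes.

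The design, fixed before the data were examined, assumed counts and named a count model. As the deposited values were RPKM, limma 3.58.1 in R 4.3.3 was chosen instead, on log2(RPKM + 0.5) with a variance trend. The recovered reads would also have allowed the planned count model, which was not run. Genes with RPKM of at least 1 in at least 3 libraries of the fit were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each line was fitted alone. The average response was fitted over all 18 libraries with cell line as a covariate, and the differences of response in a 6-group fit. Genes called in the same direction in all 3 lines were compared with the number that independent lists would share. The 35 gene lists fixed in the design were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. No list passed with the estimated correlation. The mitochondrially encoded list had no member in the table, and the fibroblast list had fewer than 3 members tested in K562. R was used with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

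The fits were tested on simulated data with a common spread for all genes of a line, taken from its libraries. Real genes differ in spread, so the shares recovered and false calls may differ in the real data. Of genes changed 1.5-fold, 90% were called in K562, 64% in the libraries labelled KMS34 and 82% in HEK293. At 2-fold 96% were called in each line. False calls were 9 of 11421 unchanged genes, 19 of 11728 and 10 of 12662. Camera called 0 of 30 null lists in each line. The simulated genes were drawn independently, so this does not test camera where genes vary together. Other groupings of the real libraries of a line gave up to 17 called lists in K562, 16 in the libraries labelled KMS34 and 9 in HEK293.

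The genes named were chosen by a rule written beforehand, read in RPKM where it had said CPM. It took CUL1, the 8 largest rises and falls per line among called genes with a mean of at least 5 RPKM in the higher group and no overlap between the libraries of the 2 groups, up to 4 members per list by adjusted p, the 8 largest shared rises and falls with at least 5 RPKM in each line, and the 5 genes with the smallest adjusted p per difference. Sex-linked marker genes, immunoglobulin and T cell receptor segments and genes with only a clone name were left out of it. HBE1, HBG1 and the other markers of cell identity were looked up because the profile did not go with the label.

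Whether replicate numbers pair the libraries was checked by correlating, across genes, the deviations from the group mean of libraries with the same number. In K562 these were 0.37, 0.15 and 0.44, all above 0.1, so the value with a replicate block is given beside the K562 count. Libraries with unlike numbers reached 0.03 in K562, 0.28 in the libraries labelled KMS34 and 0.13 in HEK293. With 3 libraries per group, same numbers can match best by chance, so pairing in K562 is not established. In the libraries labelled KMS34 and in HEK293 at least 1 was below 0.1.

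Alternatives planned beforehand were no filter and a stricter filter, a replicate block, a 6-group fit, robust estimation, each library left out and each line left out. Chosen after the unit was known were pseudocounts of 0.1 and 1, median-of-ratios, upper-quartile and quantile scaling of the RPKM values and limma-voom on the recovered reads. These stand in for the planned count scalings and the planned second count model, which were not run on RPKM. Overlap without the libraries labelled KMS34 and lists without the shared genes were also added then. No library was left out of the reported values.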

Results

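RNA was profiled in 3 human cell lines after 44 h with 12 µM of an antisense oligonucleotide (ASO), a short synthetic nucleic acid that pairs with RNA. One oligonucleotide was a non-targeting scramble, and the other targeted ncpCUL1, an RNA that the series relates to intronic polyadenylation and to the nucleolus. K562 is a chronic myelogenous leukaemia line with erythroid features, KMS34 is a multiple myeloma line, and HEK293 is an embryonic kidney line. Each line and oligonucleotide had 3 libraries, which gave 6 groups and 18 libraries. K562 was treated in medium with 1% serum and KMS34 in medium with 7.5% serum, and the labels tie a further medium to no line, so line and medium changed together. The libraries held from 19682322 to 29386747 reads assigned to genes. The deposited values are RPKM over coding length, and fold changes are on the scale of log2(RPKM + 0.5). Gene positions are those of RefSeq on GRCh38.p14, and the submitters name hg38. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. No untreated libraries were analysed here.

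The first question was what the files show of the target gene. CUL1 encodes the scaffold of an SCF ubiquitin ligase and lies on chromosome 7 at 148697756 to 148801110. The values count reads over coding sequence, so an RNA that ends within an intron need not be in them. In K562, CUL1 was at 88.7 ± 0.84 RPKM (SD, n = 3) with the scramble and 82.4 ± 0.83 RPKM with the ncpCUL1 oligonucleotide, without overlap between the libraries. The log2 fold change of -0.11 ± 0.05 (SE) did not pass the test (limma adjusted p = 0.17, or 0.067 with the replicate number as a block). This SE rests on a variance that limma draws toward that of other genes, and it exceeds the spread of CUL1 itself. A small fall in K562 is thus not excluded. Of genes tested in K562, 34.9% had no overlap, against 10% by chance. In the libraries labelled KMS34, its log2 fold change was -0.08 ± 0.07 (limma adjusted p = 0.63). In HEK293 it was 0.05 ± 0.07 (limma adjusted p = 0.78). The gene neighbours of CUL1 did not pass as a list in any line, with limma camera adjusted p = 0.30 in K562, 0.86 in the libraries labelled KMS34 and 0.24 in HEK293. In K562, PDIA4 of that list rose and ZNF777 and ZNF212 fell (the same count when adjusted over the list alone). PDIA4 also rose in the libraries labelled KMS34, as the 1 gene called of 11 tested there (1 when adjusted over the list alone). PDIA4 is also in the list of unfolded protein response genes. Of the 21 genes of that list, 12 rose in K562, 4 in the libraries labelled KMS34 and 0 in HEK293. The rise of PDIA4 can therefore not be read as an effect at the CUL1 locus. EZH2, a histone methyltransferase gene at 148807383 to 148884291 beside CUL1, rose in HEK293 from 96.8 ± 4.92 to 121 ± 3.34 RPKM (limma adjusted p = 0.037).

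**Figure D1:**
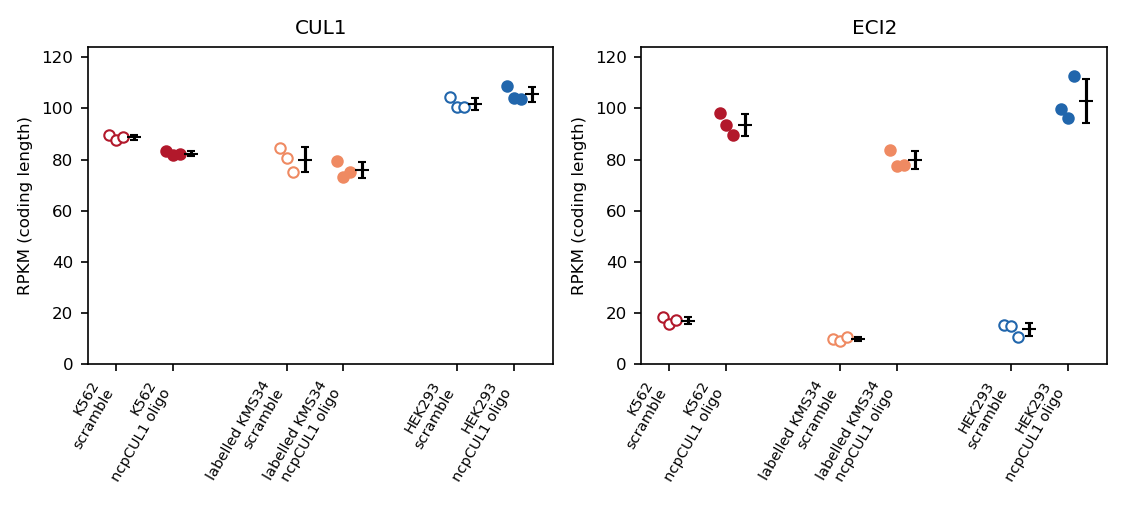
RPKM of CUL1 and ECI2 in each library (open circles, scramble, filled circles, ncpCUL1 oligonucleotide, bars, mean ± SD of 3 libraries). Group means of CUL1 ran from 75.9 to 106 RPKM, and ECI2 went from group means of 9.81 to 16.98 RPKM with the scramble to 79.8 to 103 RPKM with the ncpCUL1 oligonucleotide.

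The marker genes of the libraries labelled KMS34 did not go with the label. Fetal and embryonic globin genes were abundant, with scramble means of 2937 ± 68.0 RPKM for HBG1 and 6206 ± 368 RPKM for HBE1 (SD, n = 3). In K562 these were 2711 ± 78.9 and 5807 ± 180 RPKM. GATA1, an erythroid transcription factor gene, was at 370 ± 10.9 RPKM in the libraries labelled KMS34 and 308 ± 17.6 RPKM in K562. Of 20 plasma cell markers in the table, 5 were at 5 RPKM or more in the libraries labelled KMS34 (XBP1, NSD2, CCND1, CCR10 and DERL3), and 5 were so in K562, with 0 in the former only. IRF4 reached at most 0.10 RPKM, TNFRSF17 0.17 RPKM and SDC1 2.26 RPKM in any of the 6 libraries. MTAP, CDKN2A and CDKN2B, neighbours on chromosome 9, had 0 reads in each of the 6 libraries and in each of the 6 of K562, whereas HEK293 had scramble means of 52.7 ± 1.07, 464 ± 17.5 and 6.78 ± 1.63 RPKM. Across 14028 genes, log2 values of these libraries correlated with those of K562 at r = 0.969 to 0.983, and with those of HEK293 at r = 0.691 to 0.715. This is a correlation across genes, which are not independent replicates. The lowest correlation between replicates of a group, over the same genes, was 0.992. These 6 libraries are named below by their label, and K562 and the libraries labelled KMS34 are not counted as independent cell types.

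**Figure D2:**
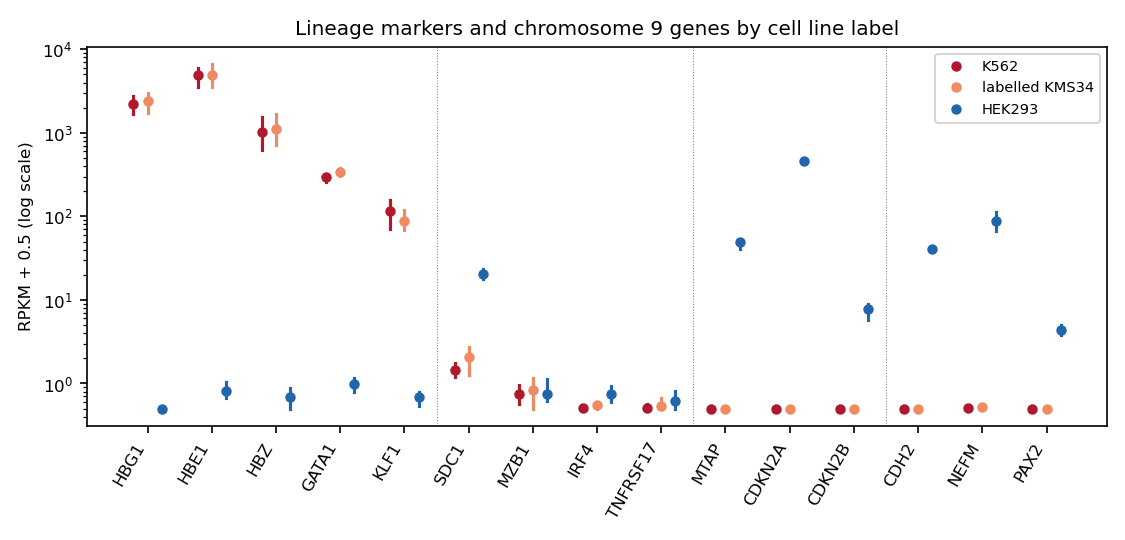
RPKM plus 0.5 on a log axis for erythroid genes (HBG1 to KLF1), plasma cell genes (SDC1 to TNFRSF17), chromosome 9 genes (MTAP to CDKN2B) and genes of HEK293 (CDH2 to PAX2). Points are means and lines ranges over the 6 libraries of a line. The libraries labelled KMS34 and K562 lie close together, as at GATA1 with scramble means of 370 and 308 RPKM against 0.60 RPKM in HEK293.

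In K562, ECI2, a fatty acid oxidation enzyme gene on chromosome 6 at 4115706 to 4135575, rose 5.39-fold, from 16.98 ± 1.34 to 93.7 ± 4.27 RPKM (limma adjusted p = 1.0e-07). SERPINC1, the antithrombin gene, rose 5.37-fold and COL6A3, a collagen VI chain gene, 3.74-fold. SPRR2D, a member of a family of similar epidermal genes that can share reads, rose 3.56-fold, CYFIP2 3.46-fold and the interleukin receptor gene IL20RB 3.44-fold. MCEMP1 and OSCAR, genes of myeloid surface proteins, rose 3.28-fold and 3.25-fold. The largest falls were in CXCL8, the interleukin 8 gene, from 294 ± 144 to 60.03 ± 22.4 RPKM (4.61-fold, limma adjusted p = 0.0066), C11orf96 (2.24-fold) and ACTL8 (2.12-fold). FAM178B fell 1.93-fold, the dehydrogenase gene DHRS2 1.86-fold, and the embryonic globin gene HBZ 1.78-fold, from 1305 ± 219 to 738 ± 168 RPKM. MYC, a growth regulator gene, fell 1.67-fold, from 321 ± 31.9 to 191 ± 12.7 RPKM (limma adjusted p = 0.00041).

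Of 11679 genes tested in K562, 1071 rose and 701 fell. Of these, 72 rose and 11 fell at least 2-fold. With the replicate number as a block, 2017 rose and 1668 fell. Leaving out 1 library gave between 711 and 1862 called genes.

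Genes of 2 stress programmes rose together in K562. Of 28 integrated stress response genes, 16 rose and none fell (18 rose when adjusted over the list alone), with camera adjusted p = 1.5e-07 and adjusted p = 0.11 with an estimated correlation. NUPR1, a stress-induced chromatin protein gene, rose from 20.4 ± 4.04 to 63.1 ± 2.0 RPKM, the serine synthesis gene PHGDH 1.63-fold and the asparagine synthetase gene ASNS 1.51-fold. Of 21 unfolded protein response genes, 12 rose and none fell (14 rose when adjusted over the list alone), with camera adjusted p = 2.1e-08 and adjusted p = 0.11 with an estimated correlation. These included the endoplasmic reticulum chaperone genes HYOU1 (1.63-fold) and HSPA5, from 397 ± 11.9 to 538 ± 6.15 RPKM. Of 16 interferon-stimulated genes tested, 6 rose and 1 fell (8 and 1 when adjusted over the list alone), among them the transcription factor gene STAT2 (1.33-fold) and the antiviral gene OAS3 (1.61-fold). That list had camera adjusted p = 0.0027 and adjusted p = 0.11 with an estimated correlation. Of 28 lysosome and autophagy genes, 8 rose (9 when adjusted over the list alone), led by WIPI1 at 1.90-fold, with camera adjusted p = 0.0023 and adjusted p = 0.28 with an estimated correlation. Of 19 apoptosis regulator genes, 4 rose (5 when adjusted over the list alone), with camera adjusted p = 0.020 and adjusted p = 0.20 with an estimated correlation. Of these 4, BMF, CASP8 and BAK1 promote apoptosis and BCL2L1 is known for a form that opposes it.

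In K562 more members fell than rose in the nucleolar structure and rRNA processing lists, while most members did not pass. Of 30 nucleolar structure genes, 13 fell and none rose (20 fell when adjusted over the list alone), with a median log2 fold change of -0.18. Nucleolin (NCL) fell from 453 ± 4.01 to 357 ± 20.1 RPKM and SURF6 from 83.6 ± 1.12 to 67.0 ± 2.46 RPKM. That list had camera adjusted p = 1.0e-09 and adjusted p = 0.11 with an estimated correlation. Of 41 small subunit rRNA processing genes, 8 fell and 1 rose (12 and 1 when adjusted over the list alone), with camera adjusted p = 2.8e-06 and adjusted p = 0.30 with an estimated correlation. Of 40 large subunit rRNA processing genes, 11 fell and 2 rose (17 and 2 when adjusted over the list alone), with camera adjusted p = 4.4e-06 and adjusted p = 0.34 with an estimated correlation. Among the latter, NOP16 fell 1.28-fold while MRTO4, a ribosome assembly factor gene, rose 1.92-fold. Of 18 RNA polymerase I transcription genes 2 rose, POLR1C (1.5-fold) and TAF1A (1.28-fold), and the list did not pass (limma camera adjusted p = 0.69). Its median was -0.03 and its mean 0.03. Of 78 cytosolic ribosomal protein genes, 0 passed in limma (0 when adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 with limma-voom). The list passed at a median of -0.04, with camera adjusted p = 0.027 and adjusted p = 0.74 with an estimated correlation. Its direction turned under quantile normalization and without scramble replicate 1, where it did not pass (camera adjusted p = 0.75 and 0.72).

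Of 30 MYC target genes in K562, 19 fell and 2 rose (19 and 2 when adjusted over the list alone), with camera adjusted p = 4.7e-09 and adjusted p = 0.11 with an estimated correlation. The spermidine synthase gene SRM fell 1.24-fold. The MYC target list shares NCL, NPM1, NOLC1, GNL3 and BOP1 with the nucleolar structure list. It shares PPAN, MRTO4, NOP16 and BOP1 with the large subunit list, and HSPD1 and HSPE1 with the heat shock list. The results of these lists are thus not separate evidence. Of 34 DNA replication genes, 8 fell (8 when adjusted over the list alone), among them MCM3 (1.18-fold), with camera adjusted p = 3.6e-05 and adjusted p = 0.11 with an estimated correlation. Of 32 mitosis genes, 8 fell and 1 rose (13 and 1 when adjusted over the list alone), among them CENPA (1.38-fold), with camera adjusted p = 3.9e-07 and adjusted p = 0.28 with an estimated correlation. Immediate early genes gave 4 falls of 22 (4 when adjusted over the list alone), which were MYC, JUND, FOSB and KLF6, with camera adjusted p = 0.0042 and adjusted p = 0.45 with an estimated correlation. NF-kB and inflammatory genes gave 2 falls of 17, CXCL8 and NFKBIA (6 when adjusted over the list alone), with camera adjusted p = 0.0059 and adjusted p = 0.64 with an estimated correlation. Heat shock genes gave 3 falls of 19, HSPE1, FKBP4 and HSPD1 (3 when adjusted over the list alone), with camera adjusted p = 0.0032 and adjusted p = 0.60 with an estimated correlation. Genes of 3' end processing gave 3 falls of 26 (2 when adjusted over the list alone), with camera adjusted p = 0.015 and adjusted p = 0.39 with an estimated correlation. Nuclear speckle and paraspeckle genes gave 3 falls of 14, SRSF2, SRSF3 and PSPC1 (3 falls and 1 rise when adjusted over the list alone), with camera adjusted p = 0.031 and adjusted p = 0.22 with an estimated correlation.

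Histone and erythroid genes also fell in K562. Of 17 replication-dependent histone genes, 13 fell and none rose (16 fell when adjusted over the list alone), at a median of -0.49. HIST1H2BK, now named H2BC12, fell from 2179 ± 158 to 1543 ± 75.7 RPKM. The list had camera adjusted p = 2.7e-10 and adjusted p = 0.20 with an estimated correlation. Histone genes are a multigene family whose members can share reads, and their main transcripts lack a poly(A) tail, so poly(A) selection records only a part of them. Of 23 erythroid and megakaryocytic genes, 11 fell and none rose (13 fell and 1 rose when adjusted over the list alone), at a median of -0.24. HBG1 fell from 2711 ± 78.9 to 1774 ± 92.0 RPKM and HBA1 from 723 ± 67.0 to 465 ± 12.3 RPKM. HBG1 and HBG2, and HBA1 and HBA2, are near-identical pairs whose reads the counting could split. The list had camera adjusted p = 7.7e-08 and adjusted p = 0.11 with an estimated correlation.

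In the libraries labelled KMS34, ECI2 rose 7.80-fold, from 9.81 ± 0.85 to 79.8 ± 3.44 RPKM (limma adjusted p = 7.5e-07). BHMG1, now named MEIOSIN, rose 6.86-fold from 0.46 ± 0.22 RPKM, PACSIN2, an endocytosis adaptor gene, 4.63-fold and TDRD7 3.94-fold. SERPINC1 rose 3.42-fold, BTRC, an F-box gene of SCF ligases, 3.22-fold, the collagenase gene MMP1 2.85-fold and the nuclear import gene IPO11 2.70-fold. CPXM1 fell 3.43-fold, from 9.95 ± 2.17 to 2.51 ± 0.25 RPKM, PGLYRP4 2.52-fold, DEPP1 2.48-fold and COL11A2 2.38-fold. CXCL8 fell 2.37-fold and the histone gene HIST2H3D, now named H3C13, 2.71-fold. Of 11966 genes tested, 252 rose and 203 fell. Of these, 43 rose and 23 fell at least 2-fold. Leaving out scramble replicate 3 gave 1317 called genes, and leaving out ncpCUL1 oligonucleotide replicate 3 gave 105.

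Erythroid and histone genes fell in the libraries labelled KMS34 too. Of 23 erythroid and megakaryocytic genes, 12 fell and none rose (20 fell when adjusted over the list alone), at a median of -0.57. HBA1 fell from 939 ± 35.7 to 452 ± 31.6 RPKM and HBZ from 1500 ± 231 to 753 ± 44.6 RPKM. The list had camera adjusted p = 6.8e-20 and adjusted p = 0.10 with an estimated correlation. Of 17 histone genes, 11 fell and none rose (15 fell when adjusted over the list alone), at a median of -0.63, with camera adjusted p = 1.6e-15 and adjusted p = 0.058 with an estimated correlation. Of 23 cholesterol synthesis genes, 5 fell (13 when adjusted over the list alone), including INSIG1, from 192 ± 11.3 to 115 ± 4.84 RPKM, and MSMO1 (1.43-fold), with camera adjusted p = 2.6e-07 and adjusted p = 0.14 with an estimated correlation. Of 13 fatty acid synthesis genes, FASN and ELOVL6 fell (5 fell when adjusted over the list alone), with camera adjusted p = 0.00069 and adjusted p = 0.97 with an estimated correlation. Of 21 unfolded protein response genes, 4 rose, HYOU1, PDIA4, MANF and CRELD2 (6 when adjusted over the list alone), with camera adjusted p = 6.4e-06 and adjusted p = 0.14 with an estimated correlation. Of 18 interferon-stimulated genes, CMPK2 and MX2 rose (4 when adjusted over the list alone), with camera adjusted p = 0.0039 and adjusted p = 0.97 with an estimated correlation. The integrated stress response list did not pass there (median -0.04, limma camera adjusted p = 0.89), with 1 rise and 1 fall among 27 genes (1 and 2 when adjusted over the list alone). The nucleolar structure list did not pass there either (median -0.07, limma camera adjusted p = 0.14), and 0 of its 30 genes passed in limma (1 at an unadjusted p under 0.05, 0 with limma-voom).

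In HEK293, ECI2 rose 7.39-fold, from 13.6 ± 2.55 to 103 ± 8.75 RPKM (limma adjusted p = 2.0e-08). LY6G6C and MPIG6B, which overlap on chromosome 6 at 31718648 to 31721746 and 31720296 to 31726714, rose 7.02-fold and 6.55-fold from 1.5 ± 0.97 and 1.40 ± 0.58 RPKM. Without strand, reads in their overlap cannot be given to one of them. CCDC17 rose 2.94-fold, MRTO4 2.93-fold, from 30.8 ± 2.18 to 91.1 ± 4.93 RPKM, INHBE, an activin subunit gene, 2.76-fold, KDM3B, a histone demethylase gene, 2.53-fold and ASIP 2.31-fold. Falls were smaller, with NUDT18 falling 1.84-fold, the BMP antagonist gene NOG 1.79-fold, HNRNPH3, a splicing factor gene, 1.64-fold and SLC37A4, a glucose 6-phosphate transporter gene, 1.63-fold. Of 12914 genes tested, 152 rose and 76 fell. Of these, 42 rose and 1 fell at least 2-fold. With the replicate block 368 rose and 233 fell, without a filter on low values 40 rose and 4 fell, and leaving out 1 library gave between 59 and 411 called genes.

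Of 28 integrated stress response genes in HEK293, 5 rose and none fell (5 when adjusted over the list alone), at a median of 0.23. TRIB3 rose from 24.1 ± 1.63 to 51.0 ± 10.6 RPKM and NUPR1 from 42.9 ± 10.5 to 91.2 ± 9.0 RPKM. The list had camera adjusted p = 7.1e-07 and adjusted p = 0.96 with an estimated correlation. The unfolded protein response list did not pass (limma camera adjusted p = 0.75), with 0 of its 21 genes called in limma (1 at an unadjusted p under 0.05, 0 with limma-voom). Of 31 glycolysis and hypoxia genes, 4 fell, PDK1, ANKRD37, NDRG1 and PGK1 (10 fell and 1 rose when adjusted over the list alone), with camera adjusted p = 4.0e-09 and adjusted p = 0.72 with an estimated correlation. Of 14 histone genes, HIST1H2BK and HIST1H3B, now H2BC12 and H3C2, fell (the same count when adjusted over the list alone), at a median of -0.29, with camera adjusted p = 8.2e-05 and adjusted p = 0.72 with an estimated correlation. Of 22 cholesterol synthesis genes, STARD4 fell (3 fell when adjusted over the list alone), with camera adjusted p = 0.00020 and adjusted p = 0.75 with an estimated correlation. Of 40 large subunit rRNA processing genes, MRTO4 and DDX31 rose (2 when adjusted over the list alone), at a median of 0.09, with camera adjusted p = 0.0087 and adjusted p = 0.96 with an estimated correlation. The nucleolar structure list was at a median of 0.01 and did not pass (limma camera adjusted p = 0.86), with 0 of its 30 genes called in limma (0 at an unadjusted p under 0.05, 0 with limma-voom).

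**Figure D3:**
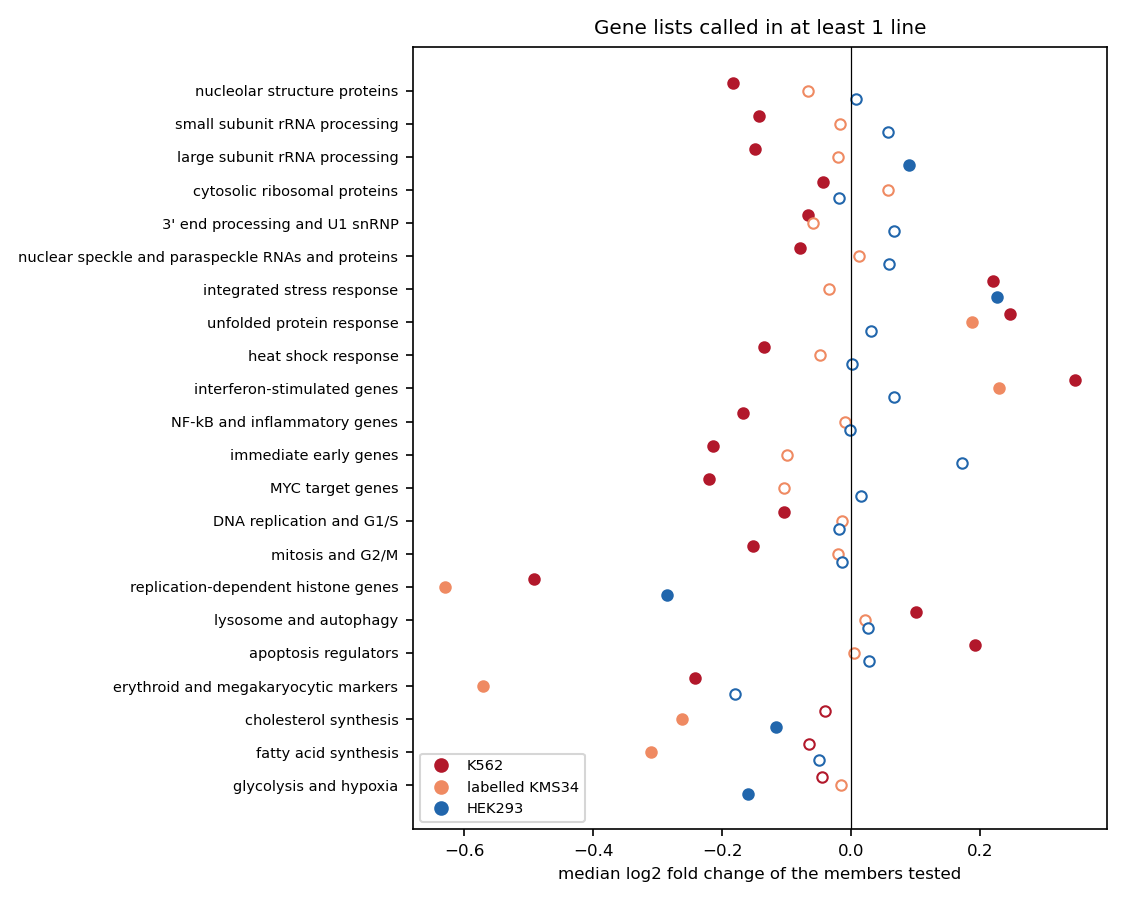
Median log2 fold change of each gene list that camera called in at least 1 line, by line. Filled circles passed camera with a preset correlation and open circles did not. The histone list lies at -0.49 in K562, -0.63 in the libraries labelled KMS34 and -0.29 in HEK293.

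The same direction in all 3 lines was seen for 34 of 10718 genes tested in each, with 31 rises and 3 falls. Independent lists of these sizes would share 0.20 rises and 0.049 falls. K562 and the libraries labelled KMS34 are not counted as independent, and their lists overlapped. Those 2 lists shared 148 rises and 99 falls, where independent lists would share 21.95 and 12.21. The figures for 3 independent lists are thus too low a reference for the 34 genes. The lines have separate scramble libraries, so their lists share no controls. By the smallest of their 3 fold changes, and with at least 5 RPKM in each line, the largest shared rises were in ECI2, KDM3B, PLSCR1, a phospholipid scramblase gene, PACSIN2, IFT43, a gene of ciliary transport, MRTO4, UPP1, a uridine phosphorylase gene, and BTRC. KDM3B rose 2.33-fold in K562, 2.49-fold in the libraries labelled KMS34 and 2.53-fold in HEK293. PLSCR1 rose 2.26-fold, 2.34-fold and 2.18-fold, in that order, and MRTO4 1.92-fold, 2.19-fold and 2.93-fold. The shared falls were in the histone genes HIST1H2BK, HIST1H3B and HIST3H2A. HIST3H2A, now named H2AC25, fell 1.32-fold in K562, 1.75-fold in the libraries labelled KMS34 and 1.35-fold in HEK293. In K562 and HEK293 alone, without the libraries labelled KMS34, 71 genes rose and 19 fell in both, where independent lists would share 10.6 and 3.36. With a replicate block 55 rose and 18 fell in all 3, and without a filter 15 rose and none fell. Leaving out 1 library gave 19 to 48 shared genes, with 0 falls without ncpCUL1 oligonucleotide replicate 3 of the libraries labelled KMS34 or any 1 of the 3 of HEK293.

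**Figure D4:**
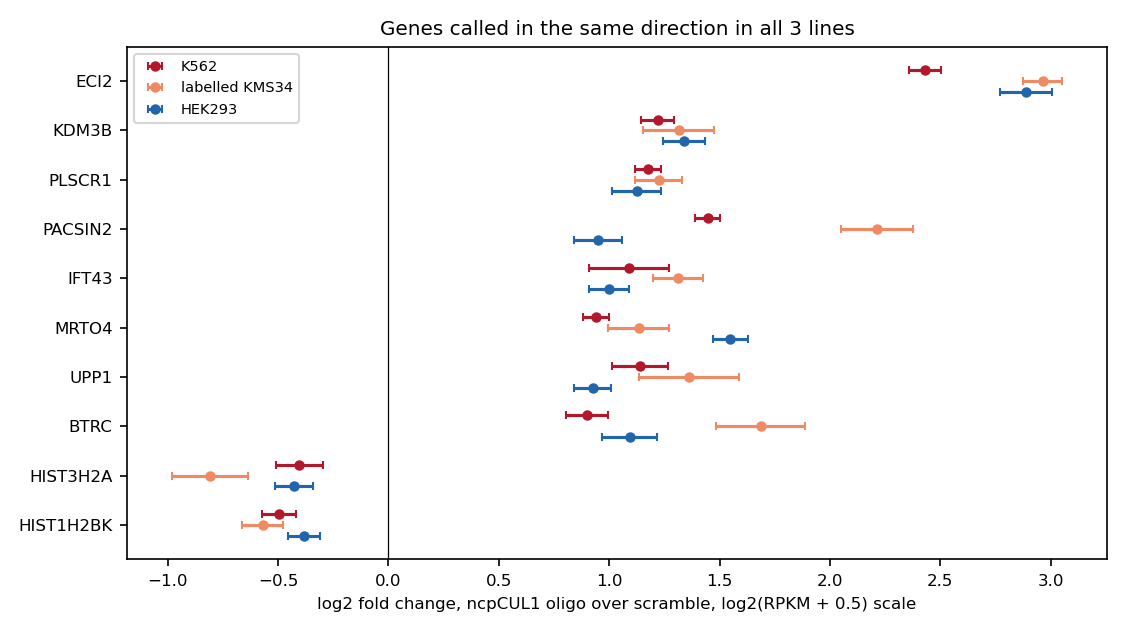
Log2 fold change (ncpCUL1 oligonucleotide over scramble) with its standard error for the 8 shared rises with the largest smallest fold change and 2 of the shared falls, by line. ECI2 lies farthest right in each line, at 2.43, 2.96 and 2.89.

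The average response over the 3 lines, fitted with cell line as a covariate, called 1190 rises and 766 falls among 14028 genes, of which 21 rose and 1 fell at least 2-fold. Median-of-ratios scaling gave 1040 rises and 1017 falls, and quantile normalization 1125 and 1087. Without K562 the average called 569 genes, without the libraries labelled KMS34 1004 and without HEK293 2145. Log2 fold changes correlated across genes at r = 0.51 between K562 and the libraries labelled KMS34, 0.32 between K562 and HEK293, and 0.33 between the libraries labelled KMS34 and HEK293. Of the 439 genes called in the libraries labelled KMS34 and tested in K562, 94.1% had the same sign in K562. For the other ordered pairs of lines the share ran from 69.8% (called in K562, sign in HEK293) to 88.6% (called in HEK293, sign in K562).

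The responses were also compared between lines directly. The difference between K562 and the libraries labelled KMS34 passed for 88 of 14028 genes, between K562 and HEK293 for 229, and between the libraries labelled KMS34 and HEK293 for 224. Leaving out 1 library gave 30 to 119, 111 to 327 and 125 to 499 genes, in that order. With limma-voom on recovered reads the second gave 109 and the third 141, and limma on only the 12 libraries of its 2 lines gave 97 for the third. SERPINC1 led the second comparison, rising in K562 from 2.18 to 14.0 RPKM while HEK293 had group means of 0.21 and 0.46 RPKM (limma adjusted p of the difference = 2.9e-05). With limma-voom that difference did not pass (limma adjusted p = 0.12), and neither did those of COL6A3, TSPOAP1, MILR1 and BHMG1. In the third, HADHB, a fatty acid oxidation gene, went from 52.0 to 106 RPKM in the libraries labelled KMS34 and from 82.6 to 83.1 RPKM in HEK293 (limma adjusted p of the difference = 3.0e-05). COL6A3, TSPOAP1, VEPH1 and MILR1, which also passed in the second comparison, were near the floor in HEK293, as SERPINC1 was. BHMG1, which passed in the third, was there too, at 0.013 and 0.19 RPKM.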

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

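The tests of a plasma cell mixture, of libraries under 2 names, of scaling and of S phase, and the comparison of splits by the direction in which the lines were turned, were chosen after the results were seen.

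The first pattern is the erythroid profile of the libraries labelled KMS34. The highest RPKM of MTAP, CDKN2A and CDKN2B in these 6 libraries was 0, as in K562, which is known to lack that part of chromosome 9, while HEK293 expressed all 3 genes. The median log2 ratio of 20 plasma cell markers to K562 was 0.0666, and 0 markers reached 5 RPKM in these libraries only. PRDM1 (2.02 and 0.52 RPKM) and CCND1 (42.0 and 18.1 RPKM) were higher there than in K562. Transcripts known to be abundant in plasma cells stayed near 0, with at most 0.10 RPKM of IRF4, 0.17 of TNFRSF17 and 0.65 of MZB1 in any of the 6 libraries, which argues against a mixture with plasma cells. The highest correlation with a K562 library was 0.983, below the lowest between replicates (0.992), which argues against the same libraries under 2 names. K562-type cells in the libraries labelled KMS34 are a candidate explanation, and whether through a library label or a culture stays open.

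The second pattern is the 31 rises and 3 falls shared by the 3 lines. Of 100 length-matched random gene sets, 89 had a 12-base word as over-represented in their transcripts as that of the 31 genes. This argues against a 12-base site for the scramble that many of the 31 share exactly in mature RNA. Different stretches of the oligonucleotide, or sites with a mismatch, would not show, so scramble sites are not excluded. The median gene length of the 31 genes, 28552 bp, was at percentile 42.2 of expression-matched sets. This argues against cleavage of pre-mRNA with the scramble that favours long genes. It does not bear on cleavage that does not depend on gene length. Without untreated libraries a rise with the ncpCUL1 oligonucleotide may be a fall with the scramble, and both tests bear on the scramble alone. Cleavage at sites of the ncpCUL1 oligonucleotide would lower RNA and was not tested, and introns were not searched. A response to the loss of ncpCUL1 that the lines share stays open as the hypothesis that the design names, untested against effects of either oligonucleotide elsewhere.

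The third pattern is the fall of erythroid and histone genes in K562 and the libraries labelled KMS34. Under 3 other scalings the list median closest to 0, over both lists and both sets of libraries, was -0.23. The median over all genes was already 0.016 in K562 and -0.003 in the libraries labelled KMS34, so these scalings had little to shift. The values show a fall of both lists relative to most genes, and do not otherwise test scaling. The DNA replication list lay above the histone list by 3.79 SD of its members in the libraries labelled KMS34 and by 3.36 SD in K562. In K562, 8 of 34 replication genes fell, and 8 of 32 mitosis genes fell and 1 rose, at smaller list medians of -0.10 and -0.15. Both lists passed camera with the preset correlation and not with an estimated one (limma camera adjusted p = 0.11 and 0.28). In the libraries labelled KMS34 the replication and mitosis lists were at medians of -0.01 and -0.02. They did not pass there (limma camera adjusted p = 0.89 for both). How far a loss of S phase cells would lower replication genes was not measured, so fewer cells in S phase are not excluded. Globin genes took 0.715% of reads with the scramble and 0.478% with the ncpCUL1 oligonucleotide in K562, and 0.808% and 0.484% in the libraries labelled KMS34. A change in the share of histone RNA with a poly(A) tail was not tested and may contribute.

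The differences of response were tested directly. Between K562 and the libraries labelled KMS34 they passed for 88 genes, between K562 and HEK293 for 229, and between the libraries labelled KMS34 and HEK293 for 224. Genes called in both lines in opposite directions were 1, 0 and 2 of these. K562 minus the libraries labelled KMS34 gave log2 differences of 1.38 for TRPV6, 1.62 for TRIM67, -0.52 for CLPTM1L, 1.67 for CPXM1 and -0.87 for BYSL. K562 minus HEK293 gave 1.99 for SERPINC1, 1.90 for COL6A3, 1.60 for TSPOAP1, 1.55 for VEPH1 and 1.20 for MILR1, all of them below 0.5 RPKM in HEK293. The libraries labelled KMS34 minus HEK293 gave 2.36 for BHMG1, 1.01 for HADHB, 0.98 for PLOD1, 0.84 for TXNDC12 and -2.33 for MPIG6B. BHMG1 was near the floor in HEK293, at 0.013 and 0.19 RPKM against 0.46 and 5.97 RPKM in the other set, so its ratio was about as large in both. With limma-voom the differences of SERPINC1, COL6A3, TSPOAP1, MILR1 and BHMG1 did not pass.

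Other splits of the same libraries were counted. For the genes called within a line, 1 of 10 splits, the real one, gave as many, and the highest other gave 0 genes in K562 (1772 in the real one), 0 in the libraries labelled KMS34 (455) and 0 in HEK293 (228). In K562, 4 splits part all 3 pairs of libraries with the same number, and the highest other of these gave 0. For lists called by camera with a preset correlation, 1 of 10 splits gave as many as the 19 in K562 (highest other 17), 9 of 10 as many as the 6 in the libraries labelled KMS34 (highest other 16) and 9 of 10 as many as the 5 in HEK293 (highest other 9). In each line 10 splits are too few for a share under 0.05. The list counts in the libraries labelled KMS34 and in HEK293 were no larger than most other splits gave. For the average response 1 of 100 splits gave as many as 1956 genes (highest other 167), which argues against a chance split there. For the shared genes 1 of 100 gave as many as 34 (highest other 0). Within each line every other split called 0 genes. Nearly all drawn splits could therefore share none, so this share cannot decide on chance.

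For the differences, 6 of 100 splits gave as many genes as the 88 between K562 and the libraries labelled KMS34 (highest other 543), so chance is not excluded there. All splits were fitted without the replicate block. Between K562 and HEK293 2 of 100 gave as many as 229 (highest other 627). Between the libraries labelled KMS34 and HEK293 2 of 100 gave as many as 224 (highest other 593). Splits within lines remove the response from both, so they stand for no response rather than for equal responses. They cannot exclude chance for a difference between 2 lines that both respond. The other splits with as many, 5, 1 and 1, all kept most treated labels in 1 of the 2 lines and turned most in the other. In those with 627 and 593 genes the turn was complete, which makes a shared response into a difference. The split with 543 kept 1 treated library in K562 and 2 in the libraries labelled KMS34. Other splits with these numbers gave 0 or 1 gene. A turned response thus does not account for the 543, and its cause was not tested. Among splits that turned the 2 lines the same way the highest others were 40, 31 and 71.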

How the results depend on the processing

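Pseudocounts, scalings, limma-voom, the overlap without the libraries labelled KMS34, lists without the shared genes and robust estimation of the joint counts and the stricter filter for shared genes were chosen after the data were seen, the rest before. Of 3734 values of 220 named genes under the alternatives, 3193 kept direction and side of the threshold, 541 lost the threshold and 0 reversed. Counted by gene, 96 of the 220 kept both under every alternative. Apart from left-out libraries and the block, 69 of 114 did in K562, 44 of 60 in the libraries labelled KMS34 and 14 of 46 in HEK293. For the 15 genes of the differences 325 of 330 values did so, the other 5 being lost with limma-voom. CUL1 passed in no line under any alternative, with a log2 range over left-out libraries of -0.11 to -0.10 in K562, -0.12 to -0.04 in the libraries labelled KMS34 and 0.03 to 0.07 in HEK293.

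The replicate block, which pairs libraries, gave 3685 genes in K562, 601 in HEK293 and 633 in the libraries labelled KMS34, and 73 shared genes. For the differences it gave 128 for K562 minus the libraries labelled KMS34 and 332 for K562 minus HEK293. For the libraries labelled KMS34 minus HEK293 it gave 329. Same-number deviations, the paired check, correlated at 0.38, -0.17 and 0.20 in the libraries labelled KMS34 and at 0.069, 0.10 and 0.14 in HEK293. The 6-group fit gave 1191 genes in the libraries labelled KMS34, 364 in HEK293 and 56 shared genes. Without a filter HEK293 had 44 genes and 15 were shared. K562 and HEK293 alone shared 90 genes. The average response called 569 genes with K562 left out, 1004 with the libraries labelled KMS34 left out and 2145 with HEK293 left out. With limma-voom the difference K562 minus HEK293 called 109 genes and that of the libraries labelled KMS34 minus HEK293 141, and limma on only the 12 libraries of the 2 lines gave 97 for the latter. The cause was not tested.

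With an estimated correlation, with or without the replicate block, 0 lists were called in K562, 0 in the libraries labelled KMS34 and 0 in HEK293, and fry called 0 one-way in HEK293. The mixed test of fry called 22 lists in the libraries labelled KMS34 and 17 in HEK293. The cytosolic ribosomal proteins list in K562 reversed with quantile normalization (limma camera adjusted p = 0.749) and without scramble replicate 1 (0.716), with a range over left-out libraries from 9.20e-06. Of 510 values of the 30 called lists 417 were kept, 91 lost the threshold and 2 reversed.

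Leaving out 1 library gave 711 to 1862 genes in K562, with 879 without scramble 2, 1046, 711 and 1113 without ncpCUL1 oligonucleotide 1, 2 and 3. In the libraries labelled KMS34 it gave 105 to 1317, with 225, 155 and 1317 without scramble 1, 2 and 3 and 159, 128 and 105 without oligonucleotide 1, 2 and 3. In HEK293 it gave 59 to 411, with 95 and 411 without scramble 2 and 3 and 140, 59 and 136 without oligonucleotide 1, 2 and 3. Shared genes ran from 19 to 48, with 20, 21, 19 and 19 without scramble 2 and oligonucleotide 1, 2 and 3 of the libraries labelled KMS34 and 20 without HEK293 oligonucleotide 2. The average ran from 1571 to 2216 genes.

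For K562 minus the libraries labelled KMS34 the range was 30 to 119 genes, with 38, 48, 52 and 41 without K562 scramble 1 and 2 and oligonucleotide 1 and 2, and 56, 30 and 42 without scramble 2 and oligonucleotide 1 and 3 of the other set. For K562 minus HEK293 it was 111 to 327, with 111, 132, 138, 120 and 149 without K562 scramble 1 and 2 and oligonucleotide 1, 2 and 3, and 147, 150 and 118 without HEK293 scramble 2 and oligonucleotide 1 and 2. For the libraries labelled KMS34 minus HEK293 it was 125 to 499, with 139, 499, 129, 146 and 125 without scramble 2 and 3 and oligonucleotide 1, 2 and 3 of the first, and 136 and 127 without HEK293 oligonucleotide 1 and 2. Called lists ran from 17 to 19 in K562, from 6 to 13 in the libraries labelled KMS34 (13 without scramble 3) and from 5 to 9 in HEK293 (8 without scramble 1, 9 without oligonucleotide 3). Depth limits genes near 1 RPKM, where few reads stand behind a value.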

Other observations

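The test of neighbouring genes was thought of after LY6G6C and MPIG6B had been seen among the largest rises in HEK293.

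Further gene lists fixed beforehand did not pass in limma camera in any line. Of 27 SCF ubiquitin ligase and neddylation genes, 2 rose in K562, BTRC and FBXL5, and BTRC alone rose in the other lines (1 in each line when adjusted over the list alone). Of 7 other cullins, CUL7 and CUL4B rose in K562, from 27.7 ± 1.41 to 37.8 ± 1.83 RPKM and from 39.7 ± 1.92 to 50.2 ± 0.65 RPKM (2 rose and 1 fell when adjusted over the list alone). Of 24 p53 target genes in K562, TP53INP1, SESN2, DDB2 and CCNG1 rose (4 rose and 1 fell when adjusted over the list alone). In HEK293, GDF15 and GADD45A of that list rose, and in the libraries labelled KMS34 GADD45A fell. Of 20 nuclear exosome genes, EXOSC8 rose and EXOSC7 and PABPN1 fell in K562 (the same counts when adjusted over the list alone), and EXOSC8 rose in the libraries labelled KMS34. Of 4 snoRNA host genes tested, C6orf48, now SNHG32, rose in K562 and in the libraries labelled KMS34. MYC fell 1.53-fold in the libraries labelled KMS34, from 371 ± 36.5 to 242 ± 2.89 RPKM (limma adjusted p = 0.0039). SLC2A1, a glucose transporter gene, fell there from 195 ± 6.66 to 112 ± 4.21 RPKM. BYSL, a small subunit assembly gene, rose 2.18-fold there and 1.43-fold in HEK293.

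Of 32 respiratory chain genes 0 passed in K562 in limma (2 at an unadjusted p under 0.05, 0 with limma-voom), 1 rose in the libraries labelled KMS34 (0 when adjusted over the list alone) and 0 passed in HEK293 (1 unadjusted, 0 with limma-voom). Of 19 oxidative stress genes TALDO1 fell in K562 (1 when adjusted over the list alone). Of 6 plasma cell markers tested in K562, XBP1 rose and DERL3 fell (2 rose and 1 fell when adjusted over the list alone). Of 10 in HEK293, 1 rose and 1 fell (the same when adjusted over the list alone), and of 9 in the libraries labelled KMS34 0 passed (1 unadjusted, 0 with limma-voom). Of 13 embryonic kidney and neural-lineage markers in K562, 4 rose and 2 fell (5 and 2 when adjusted over the list alone), and VIM rose from 1659 ± 42.7 to 2543 ± 254 RPKM. In HEK293 NEFL and NEFM of 18 fell (2 when adjusted over the list alone). Of 5 fibroblast markers 0 passed in the libraries labelled KMS34 (2 unadjusted, 1 with limma-voom) and 0 in HEK293 (1 unadjusted, 0 with limma-voom). List median, mean and camera direction differed in sign for 5 lists in K562, 11 in the libraries labelled KMS34 and 6 in HEK293, of which 0 were called.

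A hypothesis was that genes rising in HEK293 are neighbours more often than chance. Among 152 risen genes, 5 pairs of neighbouring tested genes both rose, against a median of 2 in 10000 random draws, and 326 draws had as many. These include 2 pairs with LY6G6C or MPIG6B, which prompted the test. Without those 2 genes 3 pairs were left, and 2552 of 10000 draws had as many, so the hypothesis is not supported in HEK293. In K562 126 pairs did (median 98, 19 of 10000 draws) and in the libraries labelled KMS34 10 (median 5, 406 of 10000 draws). The 2 pairs were of LY6G6C, MPIG6B and DDAH2 on chromosome 6, with starts at 31718648, 31720296 and 31727040. Overlapping genes share reads in non-directional libraries, and transcription that runs on from one gene into the next may also give such pairs, so the 5 pairs do not show regulation of the region.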
